A study of Mus musculus with 9 samples.

How the data were processed

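Mouse CD8+ T cells were kept for 4 days with IL-2, IL-15 or IL-21 at 10 ng/ml, or with no cytokine, and were then stimulated again for 4 h with no cytokine present. Each of the 9 two-colour oligonucleotide arrays set RNA of cytokine-treated cells against RNA of untreated cells, with 3 biological replicates per cytokine. RNA was amplified and labelled by amino allyl coupling, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

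The deposited table of the series holds 1 value per probe and array for 36547 probes, with no missing value. The deposited values were taken as log2 ratios, because they are signed, lie around 0 and run from -8.01 to 8.78. That range is too wide for a log10 scale, but a natural log is not excluded, in which case every log2 change given here would be too small by the same factor. The scanner, the background correction, the normalization and the log base are not given in the sources used here. Array medians were -0.04, -0.04 and -0.05 for IL-2, IL-15 and IL-21 in replicate 1, 0.02, 0.03 and 0.06 in replicate 2, and 0.13, 0.02 and 0.01 in replicate 3. The submitters' normalization was kept.

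The direction of the ratios is likely, not settled. The labels put cytokine-treated cells in Cy5 on every array, while the series design text states that the dyes were exchanged in replicate 2 and in replicate 3 of IL-2 and IL-15. It leaves out IL-21 replicate 3, for which a list deposited with the series states the exchange. A rule fixed before the data were examined compared replicate 1 with replicates 2 and 3 within each cytokine. Their correlations over all probes lay between -0.28 and 0.06, with 0.17 to 0.23 between replicates 2 and 3, and for this case the rule gave no direction. A further check was chosen after the values were seen. It used the differences between 2 cytokines within a replicate, in which a dye effect cancels. The difference of IL-21 and IL-2 correlated between replicates at 0.20, 0.15 and 0.11, and that of IL-21 and IL-15 at 0.12, 0.14 and 0.17, while that of IL-15 and IL-2 gave 0.04, -0.04 and -0.02. From the positive values all arrays were taken to run one way, and from the order of the channels in the labels that way was taken as cytokine over untreated. This departs from the fixed rule. If the channel order were the reverse, every sign given here would turn while sizes and counts would stay. With the sign of replicates 2 and 3 turned, limma called 0 genes in each of the 6 comparisons, although more genes then had an unadjusted p under 0.05 for IL-2 (1895, against 1543 unturned) and for IL-21 (1709, against 1059). Across the 36 pairs of arrays, 3 correlated below -0.3, the lowest at -0.35, and all 3 paired arrays of opposite dye orientation, 2 of them with IL-21 replicate 3. The lowest correlation between arrays of one orientation was -0.03.

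Probes were named through the platform annotation, with symbols updated by Entrez ID. Exactly 1 symbol was listed for 26926 probes and several for 203, and 9418 probes were unnamed in the table used. The 39 probes of viral or bacterial controls were left out. Probes of a gene were averaged per array, which gave 17499 genes, 5884 of them with more than 1 probe. Where probes of a named gene disagree, their range is given. Probes of histone and granzyme genes may bind RNA of related family members. No intensities are among the values, so dim probes could not be set apart, and the number of arrays limits the precision.

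Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes). The design had 1 coefficient per cytokine over all 9 arrays, with no replicate block and no dye term, and gave 6 comparisons. Each cytokine was tested against 0, and differences of coefficients compared the cytokines. P-values were adjusted by the Benjamini-Hochberg method over all genes at a threshold of 0.05. All tests were two-sided, and errors are limma's standard errors unless stated otherwise. The genes named were chosen by a rule fixed before the data were examined. For each cytokine against untreated cells and for IL-21 versus IL-2 it takes the 10 highest and 10 lowest log2 changes among genes past the threshold with the same sign in all 3 replicates. For the remaining comparisons it takes the 5 highest and 5 lowest. Where fewer than 10 genes passed in one of the 4 main comparisons, it takes the 20 genes with the smallest unadjusted p as values only. It adds up to 4 members of each gene list with the smallest p, and 14 fixed genes, of which 12 were measured. Only part of the genes that the rule takes are printed, and Ifng, Tbx21, Prdm1, Il7r, Lef1 and Bcl6 are among those left out.

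The 22 gene lists were also fixed before the data were examined. They cover naive and memory T cell genes, cytotoxic effector molecules, effector differentiation regulators and markers, cytokines and chemokines of activated CD8 T cells, early T cell activation genes, inhibitory receptors, STAT5 targets, STAT3 targets, interferon response genes, cell cycle, glycolysis, cholesterol synthesis, apoptosis and survival, NK cell receptors, homing and adhesion receptors, T cell identity genes and ribosomal proteins. The other 5 hold markers of B cells, MHC class II antigen presentation, myeloid and dendritic cells, CD4 T cells and erythroid cells. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Beside it stood camera with an estimated correlation and fry, which asks whether the genes of a list move one way and does not compare them with other genes. Replicate medians against untreated cells are list medians of single arrays. Between cytokines they are differences between the list medians of same-numbered arrays. They can therefore lie away from the median log2 change of the genes.

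Same-numbered arrays deviated together from their cytokine's mean. The correlation of these deviations was between 0.15 and 0.65 in all 9 same-numbered pairs and between -0.58 and 0.24 in the 18 other pairs, so the numbers pair the arrays, and a fit with the replicate number as a block stood beside the unblocked one. The replicate number also marks the dye orientation. A replicate effect that all cytokines share cancels between cytokines but not against untreated cells.

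The limma step was tested on simulated arrays with 200 changed genes among 17499, with the spread and the replicate effects of the real arrays. For IL-2 versus untreated it recovered 38.8%, 89.6% and 100% of genes changed by a log2 of 1, 2 and 3, with 1 false call among 153. For IL-21 versus IL-2 it recovered 11.9%, 82.1% and 98.5%, with 0 false calls among 128. With the replicate block the shares were 68.7%, 94.0% and 100%, with 7 false among 182 calls, and 47.8%, 89.6% and 100%, with 10 false among 168 calls. The simulated replicate effects sum to 0 over the replicates of each gene, and the noise was independent between genes. These false calls therefore do not cover a replicate or dye effect that fails to cancel against untreated cells.

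The alternatives tried were the replicate block, the replicate number as a random block, a dye term, centring of arrays on their medians, quantile normalization, every probe on its own, other minimums of arrays, a fit to the compared arrays alone, robust eBayes, a minimum log2 change of 1, turned signs, and leaving out each replicate. Chosen after the data were seen were the replicate block with centring, quantile normalization of the gene averages, the median over probes, and leaving out IL-2 replicate 3, the array with the widest spread. The scanner files were not analysed here.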

Results

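Mouse CD8+ T cells were cultured for 4 days with IL-2, IL-15 or IL-21, or untreated, then stimulated again for 4 h with no cytokine present. Changes in RNA level were measured after this restimulation, each cytokine against untreated cells, on 9 arrays with 3 biological replicates per cytokine. The values thus describe restimulated cells after culture with a cytokine, not cells in its presence. The values are log2 ratios of treated over untreated cells for 17499 genes, and this direction, which departs from a rule fixed beforehand that gave none, is likely rather than settled. Arrays differed more by replicate than by cytokine. Within replicate 1 the correlation over all probes was 0.67 between IL-2 and IL-15, while replicates 1 and 3 of IL-2 correlated at -0.26. Between replicates 2 and 3 the same cytokine correlated at 0.17 to 0.23. Different cytokines correlated at 0.16 to 0.27 within replicate 2 and at 0.22 to 0.48 within replicate 3. IL-2 replicate 3 had the highest array median, 0.13, and the widest spread, with 13.6% of probes beyond a log2 ratio of 1 in either direction.

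**Figure D1:**
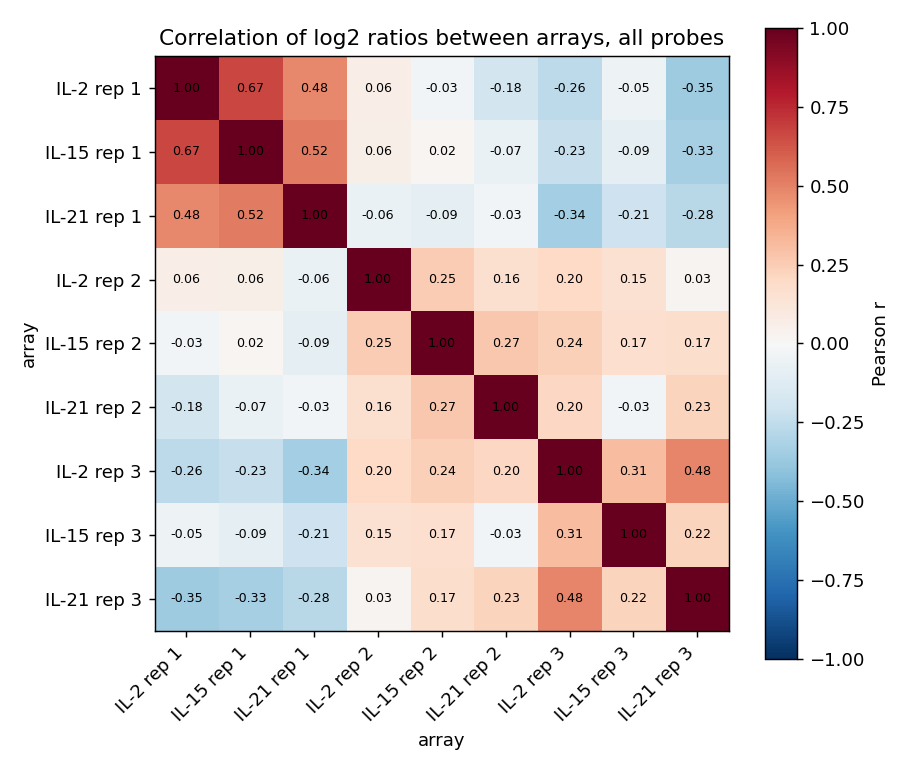
Pearson correlation of the log2 ratios of all probes between the 9 arrays, with cytokine and replicate number on both axes. Arrays of replicate 1 correlate with each other at 0.48 to 0.67 and with those of replicates 2 and 3 at -0.35 to 0.06.

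The first comparison asks which genes culture with IL-2, the main growth factor of activated T cells, changes. The growth factor gene Csf2, which encodes GM-CSF, rose by 3.66 ± 0.54 (SE; adjusted p 0.0242) and the cytokine gene Il3 by 2.38 ± 0.33 (SE; adjusted p 0.0192). S100a4, a calcium-binding protein gene of effector and memory T cells, rose by 2.59 ± 0.19 (SE; adjusted p 0.00266). Ccna2, which encodes cyclin A of dividing cells, rose by 2.15 ± 0.36 (SE; adjusted p 0.0396) and the topoisomerase gene Top2a by 2.12 ± 0.38 (SE; adjusted p 0.0472). Nr4a1 and Fos, both induced within hours of T cell receptor signals, changed by -1.50 ± 0.25 (SE; adjusted p 0.0404) and -1.37 ± 0.19 (SE; adjusted p 0.0192). Each value is a mean over n = 3 arrays that share its sign.

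With limma, 133 genes were higher and 7 lower with IL-2 at an adjusted p of 0.05, but 19 and 0 with quantile normalization, which kept 18 of the 140. With the replicate block 303 and 40 passed, but blocked p-values against untreated cells leave out the variation that arrays of a replicate share. The highest also included the cytokine gene Il24 at 2.95, the interferon-inducible gene Ifitm3 at 2.17, the microtubule regulator Stmn1 at 2.05 and the histone genes H2ac12 at 2.33 and H2ac15 at 2.08. The other lower genes were H2-Aa, which encodes an MHC class II chain, at -1.53, the signalling brake Cblb at -0.93, the glycosyltransferase gene Ogt at -0.90, the cyclin gene Ccnl2 at -0.85 and the phosphatase gene Ptpn22 at -0.76. Without replicate 1, 60 genes were higher and 9 lower. Without replicate 2 or replicate 3 limma called 0 genes, with 770 and 1138 at an unadjusted p under 0.05, and without IL-2 replicate 3 alone 6 genes were higher.

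Of the 25 measured cell cycle genes, 7 rose with IL-2, none fell and 18 did not pass, with 24 higher when adjusted over the list alone and 15 with the replicate block. Their median log2 change was 1.07 (replicate medians 1.34, 1.01 and 0.84), with camera adjusted p 2.41e-26, or 0.0651 with an estimated correlation. Bub1b, a spindle checkpoint gene, rose by 1.63 ± 0.20 (SE; adjusted p 0.0149) and Birc5, which encodes survivin, by 1.47 ± 0.22 (SE; adjusted p 0.0254). The nucleotide synthesis genes Rrm2 and Tyms rose by 1.22 and 1.11, although their single probes ranged from 0.12 to 2.32 and from 0.12 to 2.06. Of 14 glycolysis genes, 3 rose and 11 did not pass, with 8 higher when adjusted over the list alone and 5 with the replicate block. Their median was 0.56 (replicate medians 0.61, 0.73 and 0.47), with camera adjusted p 7.6e-10, or 0.0651 with an estimated correlation. These 3 were Aldoa at 1.36, Pgk1 at 1.57 and the lactate transporter gene Slc16a3 at 0.90.

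Of 15 cytokine and chemokine genes, 4 rose with IL-2 and 11 did not pass. Adjusted over the list alone, 7 were higher and 1 lower. Their median was 0.43, with camera adjusted p 9.1e-05, or 0.0651 with an estimated correlation. Beside Csf2 and Il3, these were the chemokine gene Ccl1 at 1.96 and the lymphotoxin gene Lta at 0.74. Of 20 cytotoxic effector genes, the perforin gene Prf1 rose by 1.38 ± 0.22 (SE; adjusted p 0.0359) and 19 did not pass, with 5 higher and 1 lower when adjusted over the list alone. The granzyme genes Gzma and Gzmb had 2.52 ± 0.48 (SE; adjusted p 0.0609, with the replicate block 0.00886) and 2.31 ± 0.44 (SE; adjusted p 0.0597, with the replicate block 0.0115). The cytotoxic list had a median of 0.37, with camera adjusted p 0.00529, or 0.0651 with an estimated correlation, and its adjusted p was 0.437 without replicate 1. Of 16 STAT5 targets, the cell cycle inhibitor gene Cdkn1a rose by 1.69 ± 0.17 (SE; adjusted p 0.00593) and 15 did not pass, with 5 higher when adjusted over the list alone. Their median was 0.21, with camera adjusted p 9.1e-05, or 0.0739 with an estimated correlation. The receptor gene Il2ra had 0.38 ± 0.16 (adjusted p 0.537), with single probes between -0.10 and 1.24.

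Early activation genes had a median of -0.39 (replicate medians -0.12, -0.77 and -0.56), with camera adjusted p 4.09e-08, or 0.0739 with an estimated correlation. Of 18, Nr4a1 and Fos fell, the costimulatory receptor gene Icos rose by 1.37 ± 0.19 (SE; adjusted p 0.0192) and 15 did not pass, with 1 higher and 8 lower when adjusted over the list alone and 1 and 4 with the replicate block. Naive and memory T cell genes had a median of -0.17, with camera adjusted p 0.00158, or 0.102 with an estimated correlation and 0.0664 without replicate 2. None of the 15 passed, 2 were lower when adjusted over the list alone, and 2, Id3 at -1.24 ± 0.33 (SE; adjusted p 0.197, with the replicate block 0.0174) and Cd27 at -0.97 ± 0.35 (SE; adjusted p 0.402, with the replicate block 0.0169), passed with the replicate block. MHC class II genes had a median of -0.17, with camera adjusted p 0.0036, or 0.0651 with an estimated correlation. Of 10, H2-Aa fell and 9 did not pass, and 2 were lower when adjusted over the list alone. Ribosomal protein genes had a median of -0.14, with camera adjusted p 0.0251, or 0.532 with an estimated correlation, and adjusted p values of 0.0715 without replicate 2 and 0.873 without replicate 3.

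The other 13 lists did not pass camera for IL-2. Medians were 0.25 for effector differentiation genes, of which Id2 and Batf rose by 1.14 and 1.39, -0.22 for inhibitory receptors, of which Havcr2, the gene of TIM-3, rose by 1.59, and 0.20 for cholesterol synthesis (adjusted p 0.0708, or 0.0409 with the replicate block). They were 0.04 for STAT3 targets, 0.16 for interferon response genes, 0.02 for apoptosis and survival, 0.08 for NK cell receptors, 0.08 for homing and adhesion receptors and -0.09 for T cell identity genes. The median for apoptosis and the median for homing receptors were above 0 while the test pointed down, as it did for CD4 T cell markers, and B cell and erythroid markers had means above 0 and medians below. Markers of B cells, myeloid and dendritic cells, CD4 T cells and erythroid cells had medians of -0.02, -0.08, 0.05 and -0.02. Leaving out 1 replicate brought 4 of these lists past the threshold: without replicate 1 inhibitory receptors at 0.0195 and T cell identity genes at 0.00387, and without replicate 3 cholesterol synthesis at 0.00568 and myeloid markers at 0.00396.

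**Figure D2:**
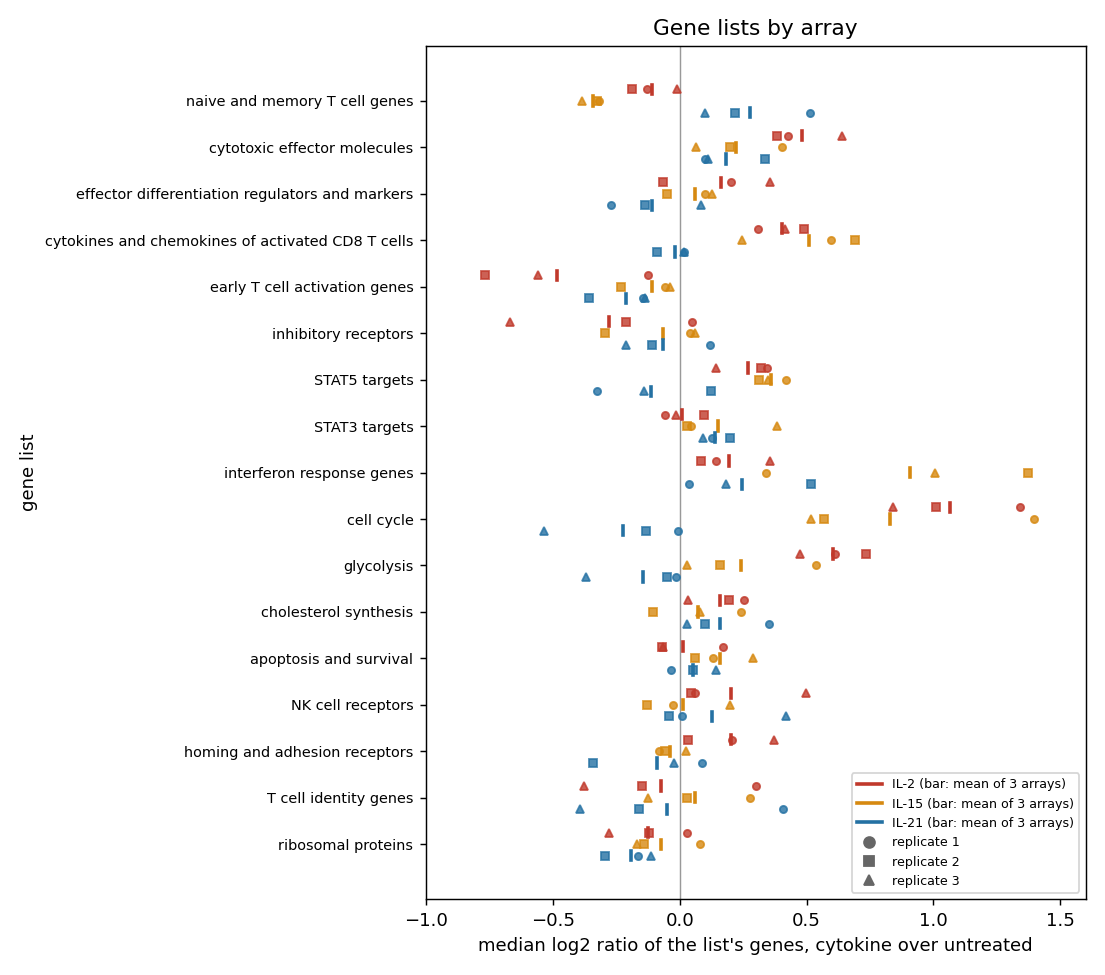
Median log2 ratio of each list's genes on each array (symbols: replicates; colours: cytokines), with bars at the mean of 3 arrays. Cell cycle genes lie between 0.52 and 1.40 on the arrays of IL-2 and IL-15 and between -0.53 and -0.01 on those of IL-21.

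IL-15 shares receptor chains with IL-2, and the second comparison asks which genes it changes. Usp18, which encodes a brake on interferon signalling, rose by 2.41 ± 0.31 (SE; adjusted p 0.0395) and the interferon-induced ubiquitin-like gene Isg15 by 2.28 ± 0.22 (SE; adjusted p 0.0206). The histone genes H2ac12 and H2ac15 rose by 2.09 ± 0.19 (SE; adjusted p 0.0163) and 1.85 ± 0.19 (SE; adjusted p 0.0206). S100a4 rose by 1.83 ± 0.19 (SE; adjusted p 0.0206). Each value is a mean over n = 3 arrays that share its sign. With limma, 22 genes were higher and 0 lower, with 893 higher and 376 lower at an unadjusted p under 0.05, and 109 and 13 with the replicate block. Quantile normalization gave 27 higher and kept 10 of the 22. The highest also included H2ac24 at 1.75, the exonuclease gene Isg20 at 1.59, the cell death gene Mlkl at 1.57, Ifitm3 at 1.46 and Phf11a at 1.45. Without replicate 1, 2 or 3 limma called 0 genes, with 1316, 621 and 1404 at an unadjusted p under 0.05.

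Of 19 measured interferon response genes, 2 rose with IL-15, none fell and 17 did not pass, with 12 higher when adjusted over the list alone. Their median was 0.77 (replicate medians 0.34, 1.37 and 1.01), with camera adjusted p 1.1e-19, or 0.0779 with an estimated correlation. Ifit3 had 2.58 ± 0.42 (SE; adjusted p 0.0738). Of 25 cell cycle genes none passed, with 18 higher when adjusted over the list alone and 6 with the replicate block, such as Ccna2 at 1.65 ± 0.36 (SE; adjusted p 0.166, with the replicate block 0.0443). Their median was 0.82 (replicate medians 1.40, 0.57 and 0.52), with camera adjusted p 6.1e-24, or 0.0734 with an estimated correlation. Cytokine and chemokine genes had a median of 0.29, with camera adjusted p 1.09e-06, or 0.0317 with an estimated correlation, the one call of any list that passed with both. None of the 15 passed, 6 were higher when adjusted over the list alone, and 5 passed with the replicate block, such as Tnf at 0.92 ± 0.14 (SE; adjusted p 0.0689, with the replicate block 0.0255) and Ccl1 at 1.71 ± 0.25 (SE; adjusted p 0.0588, with the replicate block 0.0206).

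STAT5 targets had a median of 0.33, with camera adjusted p 1.67e-07, or 0.0681 with an estimated correlation and 4 of 16 higher when adjusted over the list alone. Glycolysis genes had 0.20, with camera adjusted p 0.00057, or 0.166 with an estimated correlation and 0.294 without replicate 1, and 3 of 14 were higher when adjusted over the list alone. Cytotoxic effector genes had 0.19, with camera adjusted p 0.00215, or 0.0681 with an estimated correlation and 0.294 without replicate 1, and 2 of 20 were higher when adjusted over the list alone. Gzmb had 1.90 ± 0.44 (SE; adjusted p 0.19, with the replicate block 0.0301). Naive and memory T cell genes had a median of -0.41 (replicate medians -0.32, -0.32 and -0.39), with camera adjusted p 1.4e-05, or 0.0681 with an estimated correlation, and 1 of 15 was higher and 3 lower when adjusted over the list alone. The lymph node homing receptor gene Ccr7 had -0.47 ± 0.14 (SE; adjusted p 0.356). MHC class II genes had -0.22, with camera adjusted p 0.0494, or 0.152 with an estimated correlation, and 0.0971, 0.0632 and 0.0983 without replicates 1, 2 and 3. In these 5 lists no gene passed over all genes. The other 14 lists did not pass, with medians between -0.33 for erythroid markers and 0.13 for apoptosis and survival, and ribosomal protein genes had a median of -0.10 and a mean of 0.02. Without replicate 2 cholesterol synthesis passed at 0.012 and apoptosis at 0.0455, and without replicate 3 erythroid markers at 0.0251.

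IL-21 signals mainly through STAT3, and the third comparison asks which genes it changes. With limma, 0 genes passed for IL-21, with 458 higher and 601 lower at an unadjusted p under 0.05. This balance turned to 590 and 433 with quantile normalization and to 1142 and 703 without replicate 1. With the replicate block 11 were higher and 12 lower, and with a dye term 9 and 10, but 0 passed with the replicate number as a random block (smallest adjusted p 0.0696). The values that follow are therefore values only, over n = 3 arrays. Satb1, a chromatin organizer of naive and early T cells, had 1.42 ± 0.14 (SE; adjusted p 0.0544, with the replicate block 0.0254). Cxcr6, which encodes a chemokine receptor of tissue T cells, had 1.94 ± 0.23 (SE; adjusted p 0.0823, with the replicate block 0.0293), S100a4 had 1.69 ± 0.19 (SE; adjusted p 0.0823, with the replicate block 0.0359) and Lta had -1.08 ± 0.13 (SE; adjusted p 0.0823, with the replicate block 0.0359). Socs3, a feedback inhibitor induced by STAT3, had 1.59 ± 0.37 (SE; adjusted p 0.412, with the replicate block 0.0137). Gzma had 2.47 ± 0.48 (SE; adjusted p 0.295, with the replicate block 0.0359), the costimulatory receptor gene Tnfrsf4 had -1.69 ± 0.28 (SE; adjusted p 0.177, with the replicate block 0.0137) and the activation marker gene Cd83 had -1.70 ± 0.28 (SE; adjusted p 0.177, with the replicate block 0.0293).

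Naive and memory T cell genes had a median of 0.22 (replicate medians 0.51, 0.22 and 0.10) with IL-21, with camera adjusted p 0.000463, or 0.133 with an estimated correlation and 0.346 without replicate 1, and 4 of 15 were higher when adjusted over the list alone. STAT3 targets had 0.26, with camera adjusted p 0.00849, or 0.133 with an estimated correlation, and 2 of 13 were higher when adjusted over the list alone and with the replicate block, Socs3 and Il21, the latter at 2.19 ± 0.53. Ribosomal protein genes had -0.17, with camera adjusted p 0.000663, or 0.454 with an estimated correlation. MHC class II genes had -0.18, with camera adjusted p 0.00495, or 0.133 with an estimated correlation and 0.107 without replicate 3. Cell cycle genes had -0.23 (replicate medians -0.01, -0.13 and -0.53), with camera adjusted p 0.00495, or 0.55 with an estimated correlation and 0.556 without replicate 3. Early activation genes had -0.22, with camera adjusted p 0.00849, or 0.487 with an estimated correlation and 0.218 without replicate 2. Interferon response genes had 0.17, with camera adjusted p 0.00898, or 0.568 with an estimated correlation, and 0.0866 and 0.0644 without replicates 2 and 3.

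A further 4 lists passed camera for IL-21 near the threshold. NK cell receptor genes had 0.08, with camera adjusted p 0.0382, or 0.454 with an estimated correlation, 0.121 with the replicate block, and 0.309 and 0.446 without replicates 1 and 3. Of 13, 2 were higher when adjusted over the list alone, and the inhibitory NK receptor gene Klrc1 had 1.67 ± 0.23. Cytotoxic effector genes had 0.08, with camera adjusted p 0.0382, or 0.213 with an estimated correlation, 0.105 with the replicate block, and 0.38 and 0.0804 without replicates 1 and 3, and 2 of 20 were higher and 1 lower when adjusted over the list alone. Glycolysis genes had -0.22, with camera adjusted p 0.0423, or 0.496 with an estimated correlation, 0.0854 with the replicate block, and 0.627 without replicate 3. Cholesterol synthesis genes had 0.19, with camera adjusted p 0.0457, or 0.514 with an estimated correlation, and 0.943 and 0.0644 without replicates 1 and 3. The other 11 lists did not pass, with medians from -0.18 for inhibitory receptors to 0.07 for B cell markers. STAT5 targets passed at 0.00279 without replicate 2 and T cell identity genes at 0.00177 without replicate 1. The effector differentiation list had a median of -0.11 and a mean of 0.04, the homing list -0.09 and 0.06, and the B cell list 0.07 and -0.04. For myeloid markers both were above 0 while the test pointed down.

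The main question of the series title is how IL-21 differs from IL-2. The metallothionein genes Mt1 and Mt2, induced by metals and growth signals, were lower with IL-21, at -2.70 ± 0.32 (SE; adjusted p 0.0401) and -3.00 ± 0.35 (SE; adjusted p 0.0401). The histone genes H2ac12 and H2ac15 were lower, at -2.95 ± 0.26 (SE; adjusted p 0.0153) and -2.88 ± 0.27 (SE; adjusted p 0.0153), and the checkpoint gene Bub1b at -2.19 ± 0.28 (SE; adjusted p 0.0476). Lta was lower, at -1.82 ± 0.18 (SE; adjusted p 0.0201). Satb1 was higher by 1.49 ± 0.19 (SE; adjusted p 0.0476). Each is a mean difference over n = 3 replicates that share its sign. With limma, 1 gene was higher and 13 lower, against 5 and 87 with the replicate block and 23 and 178 with the replicate number as a random block. With quantile normalization 0 were higher and 1 lower, so that Mt1 alone of the 14 was kept and Satb1 was not (adjusted p 0.537). The other lower genes with large differences were Fignl1 at -2.37, H2bc22 at -1.86, the formin gene Diaph3 at -1.76 and H3c11 at -1.69. Without replicate 1, 2 or 3 limma called 0 genes, with 1099, 480 and 883 at an unadjusted p under 0.05, and without IL-2 replicate 3 it also called 0, with 1016.

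**Figure D3:**
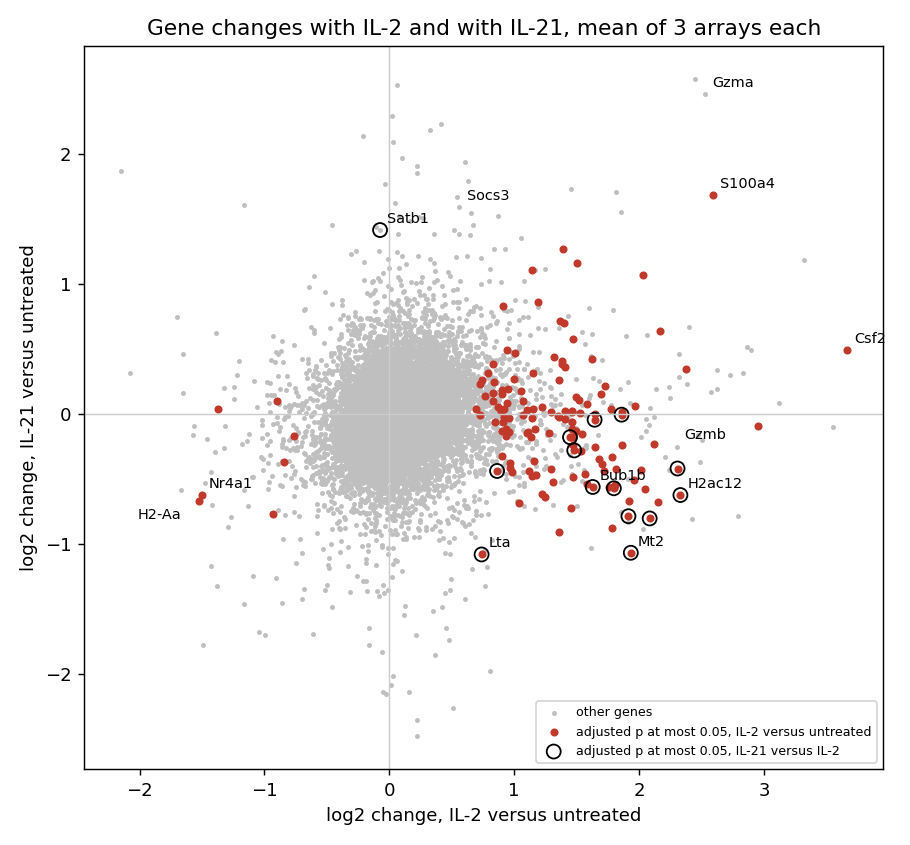
Mean log2 change of each of 17499 genes with IL-2 (x axis) and with IL-21 (y axis) against untreated cells, over 3 arrays each. Red points passed for IL-2, and the 14 circled genes passed for IL-21 versus IL-2, among them Lta, H2ac12 and Satb1.

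Of 25 cell cycle genes, Bub1b was lower with IL-21 than with IL-2 and 24 did not pass, with 18 lower when adjusted over the list alone and 7 with the replicate block, such as Ccna2 at -2.82 ± 0.51 (SE; adjusted p 0.101, with the replicate block 0.0287). Their median was -1.18 (replicate medians -1.35, -1.14 and -1.37), with camera adjusted p 7.34e-28, or 0.0664 with an estimated correlation. Here and in the later comparisons between cytokines, replicate medians are differences of array list medians, not medians of the genes' differences. Glycolysis genes had -0.77 (replicate medians -0.63, -0.78 and -0.84), with camera adjusted p 2.61e-11, or 0.0571 with an estimated correlation. None of the 14 passed, 7 were lower when adjusted over the list alone and 2 with the replicate block, such as Pgk1 at -2.02 ± 0.34 (SE; adjusted p 0.0818, with the replicate block 0.0257). STAT5 targets had -0.41, with camera adjusted p 1.1e-06, or 0.0664 with an estimated correlation, and 4 of 16 were lower when adjusted over the list alone. Naive and memory T cell genes had 0.59 (replicate medians 0.64, 0.41 and 0.11), with camera adjusted p 2.61e-10, or 0.0531 with an estimated correlation. Of 15, Satb1 was higher, also when adjusted over the list alone, and 14 did not pass, among them Klf2 at 0.92 ± 0.33 and Id3 at 1.36 ± 0.47. Early activation genes had 0.18, with camera adjusted p 0.0301, or 0.585 with an estimated correlation and 0.475 without replicate 3. Fos had 1.41 ± 0.27 (SE; adjusted p 0.114, with the replicate block 0.0369).

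The other 17 lists did not pass for IL-21 versus IL-2. STAT3 targets had 0.23 (adjusted p 0.0937, 0.0216 with the replicate block and 0.0318 without replicate 1). Cytokine and chemokine genes had -0.12 (adjusted p 0.0741). Of 15, Lta was lower, and 4 were lower with the replicate block, such as Csf2 at -3.17 ± 0.76 (SE; adjusted p 0.26, with the replicate block 0.0216) and Ccl1 at -2.46 ± 0.36 (SE; adjusted p 0.0629, with the replicate block 0.0216). Gzmb had -2.55 ± 0.62 (SE; adjusted p 0.261, with the replicate block 0.0404) and Socs3 had 1.03 ± 0.52 (SE; adjusted p 0.936, with the replicate block 0.046). Eomes, a regulator of effector and memory cells, was not among the genes that passed, and its probes had differences between -1.67 and 0.13. Its probe average was 0.41, 0.42 and 0.22 on the IL-2 arrays of replicates 1, 2 and 3. On the IL-21 arrays it was -0.77, -0.30 and -0.19. The other medians lay between -0.13 for apoptosis and survival and 0.25 for NK cell receptors. Medians and test pointed apart for inhibitory receptors, apoptosis, homing receptors, MHC class II genes and myeloid markers, and mean and median for B cell and erythroid markers.

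The title also raises whether IL-2 and IL-21 change the same genes in opposite directions. With limma, 0 genes passed in both comparisons against untreated cells, since 0 passed for IL-21. With the replicate block 1 gene, Lta, was higher with IL-2 and lower with IL-21, where 0.208 would be expected of independent lists, and 0 genes opposed with the replicate number as a random block. Also with the replicate block, Gzma, S100a4 and Cdkn2d were higher with both, where 0.19 would be expected. Cd83 and Xist were lower with both, where 0.0274 would be expected. Across 17499 genes, which are not independent, log2 changes correlated at 0.15 between IL-2 and IL-21, with a covariance of 0.0146. Simulated unchanged cytokines, with a replicate part common to same-numbered arrays, gave 0.57 and 0.0481 in 100 draws with a free replicate part. They gave 0.48 and 0.033 with a replicate part that turns with the dyes. The observed covariance differed from these by -0.0335 and -0.0185. For IL-2 and IL-15 the correlation was 0.46 and the covariance 0.0478, which differed from the simulated ones by -0.000325 and 0.0147, and for IL-15 and IL-21 they were 0.16 and 0.0146, with differences of -0.0335 and -0.0185. The simulated replicate part was sized by all variation that same-numbered arrays share, whatever its source. Its estimates below 0 were set to 0, which raises the simulated values. Differences below 0 may thus come from the simulation, and do not show that cytokines are less alike than unchanged ones. With 3 replicates the untreated cells could not be divided, so part of any overlap may come from them. IL-2 and IL-15 shared 15 higher genes, such as S100a4, H2ac12 and Ifitm3, where 0.167 would be expected of independent lists.

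**Figure D4:**
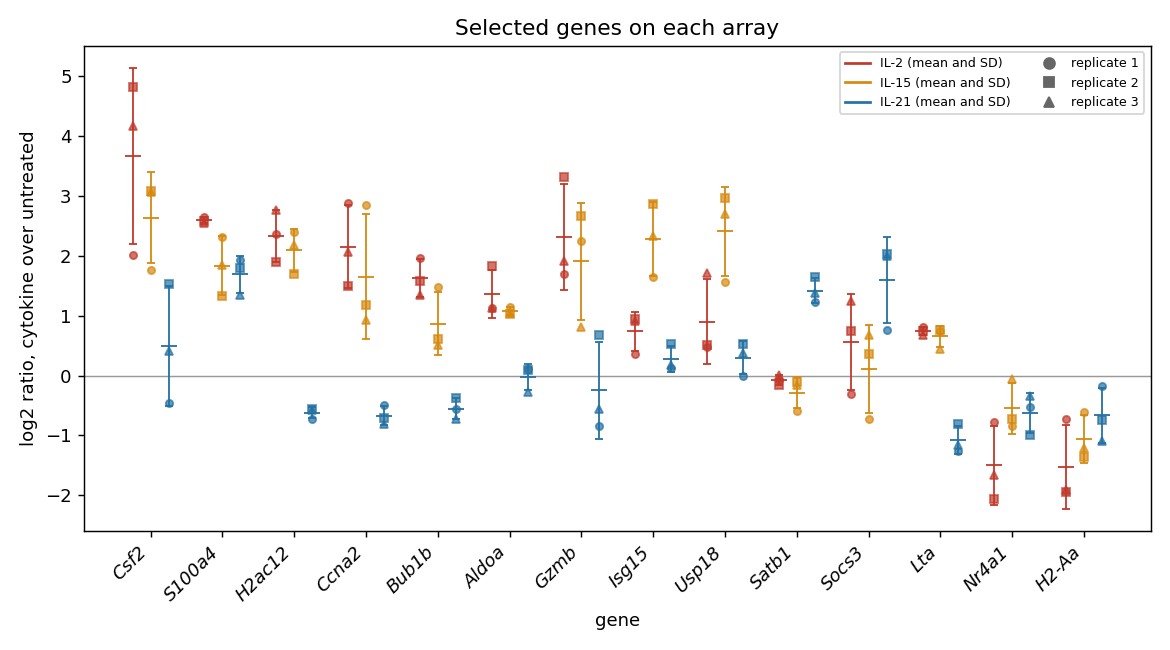
Log2 ratio of treated over untreated cells for 14 genes on each array (symbols: replicates; colours: cytokines), with mean and SD of 3 arrays. Lta lies at 0.67 to 0.81 with IL-2 and at -1.26 to -0.81 with IL-21.

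The fifth comparison sets IL-21 against IL-15. H2ac12 and H2ac15 were lower with IL-21, at -2.71 ± 0.26 (SE; adjusted p 0.0399) and -2.65 ± 0.27 (SE; adjusted p 0.0399), and Lta at -1.73 ± 0.18 (SE; adjusted p 0.0399), over n = 3 replicates. With limma these 3 were the genes that passed, with 0 higher and 3 lower, against 1 and 4 after centring of the arrays and 4 and 28 with the replicate block. With quantile normalization none of the 3 was kept (adjusted p 0.414 for H2ac12, 0.424 for H2ac15 and 0.279 for Lta) and 1 other gene passed. Satb1 had 1.70 ± 0.19 (SE; adjusted p 0.0508, with the replicate block 0.0264) and Isg15 had -2.00 ± 0.32 (SE; adjusted p 0.14, with the replicate block 0.028). Without replicate 1, 2 or 3 limma called 0 genes, with 914, 492 and 799 at an unadjusted p under 0.05, and without IL-2 replicate 3 it called 1.

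Cell cycle genes had a median of -0.99 (replicate medians -1.40, -0.70 and -1.05), with camera adjusted p 6.31e-23, or 0.1 with an estimated correlation, and 15 of 25 were lower when adjusted over the list alone. Naive and memory T cell genes had 0.61 (replicate medians 0.83, 0.54 and 0.49), with camera adjusted p 4.64e-10, or 0.0541 with an estimated correlation, and 5 of 15 were higher when adjusted over the list alone, with Ccr7 at 0.97 ± 0.19. Interferon response genes had -0.62, with camera adjusted p 4.52e-09, or 0.272 with an estimated correlation, and 6 of 19 were lower when adjusted over the list alone. STAT5 targets had -0.45, with camera adjusted p 3.18e-08, or 0.0647 with an estimated correlation, and 5 of 16 were lower when adjusted over the list alone. Glycolysis genes had -0.47, with camera adjusted p 1.39e-05, or 0.129 with an estimated correlation, and 2 of 14 were lower when adjusted over the list alone. Cytokine and chemokine genes had -0.20, with camera adjusted p 0.00624, or 0.1 with an estimated correlation, and of 15 Lta was lower, or 2 when adjusted over the list alone.

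Ribosomal protein genes had -0.07 for IL-21 versus IL-15, with camera adjusted p 0.0273, or 0.63 with an estimated correlation, and 0.176 and 0.0661 without replicates 1 and 2. NK cell receptor genes had 0.22, with camera adjusted p 0.0361, or 0.272 with an estimated correlation, 0.0925 with the replicate block, and 0.164 and 0.138 without replicates 1 and 3, and 3 of 13 were higher and 1 lower when adjusted over the list alone. STAT3 targets did not pass at 0.08 (adjusted p 0.152), but did with the replicate block (0.0412) and without replicate 3 (0.0205), with Socs3 at 1.49 ± 0.52 (SE; adjusted p 0.698, with the replicate block 0.028). T cell identity genes passed without replicate 1 (0.0486). The other 12 lists did not pass, and for effector differentiation and MHC class II genes the median was above 0 while mean and test pointed down.

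The last comparison sets IL-15 against IL-2. With limma 0 genes passed, also with the replicate block, and 87 were higher and 165 lower at an unadjusted p under 0.05, or 260 and 571 with the replicate block, but 127 and 96 with quantile normalization. Prf1 had -1.08 ± 0.32 (SE; adjusted p 1) and Ccr7 -0.53 ± 0.19 (SE; adjusted p 1), over n = 3 replicates. Interferon response genes had a median of 0.91 (replicate medians 0.19, 1.29 and 0.65), with camera adjusted p 6.24e-25, or 0.276 with an estimated correlation, and 1 of 19 was higher when adjusted over the list alone. Early activation genes had 0.27 (replicate medians 0.07, 0.54 and 0.52), with camera adjusted p 1.01e-05, or 0.312 with an estimated correlation. Glycolysis genes had -0.34 (replicate medians -0.08, -0.57 and -0.44), with camera adjusted p 3.98e-05, or 0.312 with an estimated correlation and 0.155 without replicate 2. Cell cycle genes had -0.24 (replicate medians 0.05, -0.44 and -0.32), with camera adjusted p 0.0131, or 0.76 with an estimated correlation, 0.271 without replicate 2 and 0.578 with quantile normalization. T cell identity genes did not pass at 0.12 (adjusted p 0.105), but did with the replicate block (0.0258) and without replicate 1 (0.0215). Apoptosis genes passed without replicate 1 (0.0238) and ribosomal protein genes without replicate 2 (0.0257). None of the other 17 passed with all arrays, and for STAT5 targets, STAT3 targets, cytokines, MHC class II genes and myeloid markers the median was below 0 while the test pointed up.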

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

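All tests in this part were chosen after the result was seen, except the counts of other groupings of the arrays for the 3 comparisons between cytokines.

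Replicate 1 differed from replicates 2 and 3 at 2314 genes in the blocked limma fit, 920 of them higher and 1394 lower, a difference between groups of arrays that follows no cytokine. A shift of whole arrays is argued against, since 2554 genes differed after each array was centred on its median, although the balance then turned to 1376 higher and 1178 lower. A dye effect stays open: replicates 2 and 3, which share an orientation, differed at 0 genes, while replicates 1 and 3 differed at 3072 and replicates 1 and 2 at 130. The untreated cells or the hybridisation batch of replicate 1 could give the same values. Replicate 1 had 9 probe values above a log2 ratio of 3 and 630 below -3, replicate 2 had 375 and 3, and replicate 3 had 166 and 19. The larger tail thus turned with the dye orientation. In replicate 3 the counts above were 120 for IL-2, 33 for IL-15 and 13 for IL-21. Replicate 1 alone has its dye orientation, and the set of untreated cells goes with the replicate number. These cannot be told apart, and no biological explanation was tested.

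Probes without exactly 1 gene symbol, 9660 in all with the 39 control probes, lie outside the comparisons. At an adjusted p of 0.05 in the fit over all probes, 15 of them passed for IL-2 versus untreated (12 higher and 3 lower), 1 for IL-15, 1 for IL-21 and 2 for IL-21 versus IL-2. They were not named here.

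Interferon response genes had a median of 0.77 with IL-15, with 2 of 19 higher and a camera call that did not pass with an estimated correlation (0.0779). More antigen-presenting cells with IL-15 could raise MHC class II genes, but these had a median of -0.22 (replicate medians -0.11, -0.20 and -0.17). Members ran from -1.06 to 0.39 (SD of members 0.39), with 7 of 10 below 0. H2-Aa had -1.06 ± 0.27 (SE; adjusted p 0.264, with the replicate block 0.0275). This explanation cannot be excluded, because members went both ways and may be near background. The scaling of the arrays is argued against, since the interferon median was 0.83 after quantile normalization. An effect of IL-15 itself, of its preparation, or of interferon made in the culture may remain, and none was tested. The pattern was found and tested on the same data.

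H2-Aa was lower with IL-2, at -1.53 ± 0.27, and Cd74, which encodes the invariant chain, had -0.78 ± 0.16 (SE; adjusted p 0.0803, with the replicate block 0.0173), while H2-Ab1, chosen after its value was seen, had 0.11 ± 0.15. The pattern was not particular to IL-2. H2-Aa and Cd74 were below 0 on every array, H2-Aa at -0.18, -0.74 and -1.09 with IL-21. With each cytokine 7 of 10 MHC class II genes were below 0. A part from the untreated cells, set against every cytokine, cannot be told apart. Fewer B cells could lower such genes, but the B cell markers had a median of -0.0217 (SD of members 0.10). Fewer myeloid or dendritic cells could too, and their markers had a median of -0.0822 (SD of members 0.27). Neither explanation can be excluded, because signal over background is not among the values and the markers may be near background. A change within the T cells stays open and was not tested.

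Other groupings of the arrays were counted for each comparison. For IL-2 the 4 ways of turning signs gave 140 genes for the real one and 0 at most for the others, and 1 of 4 was as large. For IL-15 they gave 22 and 0, with 1 of 4 as large, and for IL-21 0 and 0, with 4 of 4. For IL-21 versus IL-2 the 10 splits of 6 arrays gave 14 for the real one and 4 at most for the others, with 1 of 10 as large. The other 3 splits that part all same-numbered pairs gave 0. For IL-21 versus IL-15 they gave 3 and 0, with 1 of 10 as large, and for IL-15 versus IL-2 0 and 0, with 10 of 10. These are too few for a share under 0.05.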

How the results depend on the processing

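Chosen after the data were seen were the replicate block with centring, quantile normalization of the gene averages, the median over probes and leaving out IL-2 replicate 3. Counts are given in the order IL-2, IL-15 and IL-21 versus untreated, then IL-21 versus IL-2 and IL-21 versus IL-15, which without any alternative were 140, 22, 0, 14 and 3. Except where stated, the cause of a difference was not tested. IL-15 versus IL-2 stayed at 0 genes in limma under every alternative, with 81 to 831 genes at an unadjusted p under 0.05.

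With the replicate block the counts were 343, 122, 23, 92 and 32, with 1 opposing gene. It kept 138 of the 140 IL-2 calls and all 22 of IL-15. It kept all 56 calls of named genes and added 57, and kept 41 of 45 list calls and added 4. It brought STAT3 targets to 3 of the 6 comparisons (from 1), cholesterol synthesis to 2 (from 1), T cell identity genes to 1 (from 0) and NK cell receptors to 0 (from 2). Blocked values are printed beside the list calls it changed, and it changed no other list call. With the replicate block and centring the counts were 342, 143, 26, 97 and 36, with 1 opposing gene. The block removes the shared replicate part from the spread, so against untreated cells its p-values leave out that variation between replicates. With a dye term they were 284, 170, 19, 90 and 39, with 1 opposing gene, and 39 of 45 list calls were kept and 6 added. STAT3 targets passed in 2 comparisons, cholesterol synthesis in 3, NK cell receptors in 0, T cell identity genes in 2 and erythroid markers in 1. Early activation genes and interferon response genes passed in 3 each (from 4), glycolysis in 5 (from 6) and ribosomal proteins in 2 (from 3). With the replicate number as a random block (correlation 0.43) the counts were 109, 29, 0, 201 and 127, with 0 opposing genes. The smallest adjusted p for IL-21 was 0.0696, so its 23 blocked calls were lost. NK cell receptors passed in 0 comparisons, and the calls gained with the block did not pass for STAT3 targets (0.0583 for IL-21 versus IL-2 and 0.089 for IL-21 versus IL-15), T cell identity genes (0.0572) or cholesterol synthesis (0.0515).

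After centring, IL-21 had 1 gene and IL-21 versus IL-15 5. Cholesterol synthesis then passed in 0 comparisons (from 1), MHC class II in 2 (from 3) and cytokines and chemokines in 4 (from 3). Of the 56 calls of named genes, centring kept 46, quantile normalization of the probes 13, every probe on its own 24 and leaving out replicate 1 14. With quantile normalization of the probes IL-2 had 19 genes, IL-21 versus IL-2 1 and IL-21 versus IL-15 1. NK cell receptors passed in 0 comparisons, ribosomal proteins, myeloid markers and erythroid markers in 1 each, and cytokines and chemokines in 4 (from 3). The call of cell cycle genes for IL-15 versus IL-2 ended (0.578), as did those of glycolysis for IL-21 (0.0567) and MHC class II for IL-15 (0.0806). With quantile normalization of the gene averages the 5 counts were 29, 44, 1, 1 and 1. With every probe on its own they were 132 higher and 6 lower for IL-2, then 7, 1, 6 and 0, where more tests are adjusted for and single probes are not averaged.

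A fit to the compared arrays alone called 0 genes for IL-2, IL-15, IL-21 versus IL-2 and IL-21 versus IL-15 in limma, with 977, 1108, 898 and 953 at an unadjusted p under 0.05. Fewer arrays estimate the spread in this fit, but whether that accounts for the lost calls was not tested. With turned signs the same 4 counts were 0, with 1895, 978, 273 and 308 at an unadjusted p under 0.05. Requiring a value on all 9 arrays or on 1 array per cytokine moved nothing, because no value is missing.

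Leaving out 1 replicate gave 0 genes for IL-15, IL-21 versus IL-2 and IL-21 versus IL-15. For IL-2 it gave 69 without replicate 1 and 0 without replicate 2 or 3, although each left equally many arrays. At an unadjusted p under 0.05 in limma, IL-2 had 2357 genes without replicate 1, against 1543 with all arrays. The number of arrays alone thus does not account for the differences. Without replicate 1, 46 of the 69 were among the 140, and without replicate 2 or 3 all 56 calls of named genes were lost with none reversed. Without IL-2 replicate 3 the counts were 6 for IL-2, 16 for IL-15, 0 for IL-21 versus IL-2 and 1 for IL-21 versus IL-15. The lists moved between replicates left out as follows: cytotoxic effector molecules 0 to 3 comparisons, inhibitory receptors 0 to 1, STAT3 targets 1 to 2, cholesterol synthesis 0 to 2, apoptosis and survival 0 to 1, NK cell receptors 0 to 2, T cell identity genes 0 to 4, MHC class II 1 to 2, myeloid markers 0 to 1 and erythroid markers 0 to 1.

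With an estimated correlation, camera kept 1 of 45 list calls, that of cytokines and chemokines for IL-15. The lists that fell to 0 comparisons were naive and memory genes, cytotoxic effectors, early activation genes, STAT5 and STAT3 targets, interferon response genes, cell cycle, glycolysis, cholesterol synthesis, NK cell receptors, ribosomal proteins and MHC class II. With fry 23 of 45 were kept, with early activation, interferon and MHC class II genes each in 1 comparison, glycolysis in 2, and cholesterol synthesis, NK cell receptors and ribosomal proteins in 0. Cytokines and chemokines passed fry in 4 comparisons (from 3). No call of a named gene or list was reversed by any alternative run on them, but turned signs were not run on them. With turned signs 0 of the 140, 22, 14 and 3 genes called kept the sign of their change. Signal over background, which the values do not hold, limits what can be said of dim genes.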

Other observations

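Gene families were looked at after the data were seen, 19 in all, and camera was adjusted over the 19 for each comparison. Of 64 histone genes, 18 were higher with IL-2 and 25 with the replicate block, at a median log2 change of 0.62, with an adjusted p of 0.049 with an estimated correlation. With IL-15 the median was 0.55 (0.0621 with an estimated correlation). Between IL-21 and IL-2 it was -0.69 (0.0546), with 4 genes lower. The camera test pointed the same way after centring of the arrays. No other family passed with an estimated correlation in any comparison, and related histone genes share sequence, so their probes are not independent.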
